A study of Homo sapiens with 6 samples.

How the data were processed

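Gene expression was measured in bronchial epithelial cells of 3 donors, each carrying an inducible EGFP or DN-GRHL2 construct, on 6 oligonucleotide arrays with biotin-labelled, amplified RNA. The values are log2 RMA values per probe set deposited by the authors, 1 column per array. The submitters' processing notes name Affymetrix Expression Console 1.1, Partek 6.5 and RMA, with no role or order, so which of them made the final values is not given in the sources used here. All 54675 probe sets had a value on each array, from 3.10 to 14.92, with array medians of 6.72 to 6.79. At most 0.251% of probe sets had identical values on any 2 arrays, so no array was a copy of another. No scanner files were used here. The deposited values were taken as normalized between arrays, and the median difference between constructs over all tested genes was 0.02 on the log2 scale.

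Probe sets were named from the platform annotation given with the data, with symbols brought up to date through gene identifiers in a table of RefSeq genes. Of the probe sets, 41091 had 1 gene symbol, 1801 had several and 11777 were unnamed here, and 62 were array controls. The annotation's own symbol was kept for 42 genes whose identifier the table did not hold. Control probe sets and 59 probe sets of genes left out by rule were not tested. Each of the 19740 genes with a probe set was represented by the one with the highest mean over all 6 arrays among those with 1 symbol. The 30% of genes with the lowest mean, under 6.56, were left out, which left 13818. Signal near this floor limits what can be seen of dim genes. Near-identical genes, such as the class I histocompatibility genes, can share probes, and their values are uncertain.

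Groups and donors were taken from the labels, which give the donor of each array. The main fit used limma 3.58.1 in R 4.3.3 with lmFit and eBayes, the construct as the term tested and donor as a block, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. It had 2 residual degrees of freedom per gene and 2.40 prior degrees of freedom. The donor labels state the pairing. As a check, the deviations of same-donor arrays from their group means correlated across genes at 0.54, -0.06 and 0.65, against a median of -0.38 for arrays of different donors. Deviations within a group cancel out, so positive same-donor values push those between donors below 0. The -0.38 is therefore not an independent baseline. SE is limma's moderated standard error of the log2 difference and SD the spread over the 3 arrays of a group. A positive difference means higher with DN-GRHL2.

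Before the data were examined, 19 gene lists with 443 distinct genes were fixed, 15 of the genes in more than 1 list: tight junction and apical polarity, adherens junction and desmosome, epithelial genes linked to GRHL2, mesenchymal and EMT, matrix adhesion and hemidesmosome, basal cell, secretory and goblet cell, ciliated cell, squamous and cornified, proliferation, ion transport, Notch signalling, interferon response, inflammatory cytokines and NF-kB, stress and unfolded protein response, and markers of fibroblasts, leukocytes, endothelium, and ionocytes and neuroendocrine cells. Shifts of the lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 19 lists, and again with fry and with an estimated correlation, where camera also uses the 2 residual degrees of freedom in place of a number set by the genes. Members were counted past the threshold over all genes and adjusted over the list alone.

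The genes named were fixed by rule before the data were examined: the 3 grainyhead genes; up to 12 genes per direction with the largest difference among those past the threshold with 1 sign in all pairs, or the 10 with the smallest p, as values only, where none passed; and up to 3 members of each list past the threshold, or its 2 brightest members as values. After the data were seen, up to 4 members per list that passed when adjusted over the list alone, the 10 largest differences per direction at an adjusted p under 0.10, and 5 further lists were added, and a few members outside these rules are named with their values.

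The fit was tested on simulated data for this comparison over 13818 genes, with the arrays' own gene means and donor differences, variances drawn from the fitted prior, and 200 changed genes in each of 20 simulations. It recovered 29.7% of genes changed by 1 on the log2 scale, 87.6% of those changed by 2 and 96.4% of those changed by 4, with median estimates of 0.99, 2.00 and 3.99. Recovery depends on how the variances are drawn: with each gene's moderated variance instead, as tried first, it was 72.5%, 97.5% and 99.5%. The simulated changes were the same in all 3 pairs, and the noise was independent between genes. Recovery of changes that differ in size between donors was therefore not measured. In the data RSAD2 differed by 3.91 on the log2 scale with an adjusted p of 0.126 by limma over all genes.

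Alternatives covered the donor block (no replicate block, or donor as a random effect by duplicateCorrelation), the variance prior, the filter, the choice of probe sets, the scaling between arrays, the threshold and leaving out each donor pair. Added after the data were seen were an unadjusted threshold, a fit without EGFP replicate 1, the estimated correlation with the degrees of freedom of the preset test, and the counts of list members past the threshold with a pair left out, donor as a random effect or no block.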

Results

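Human bronchial epithelial cells, the lining cells of the large airways, were taken from 3 donors and grown at an air-liquid interface, a culture in which the cells face air on one side and form a layered epithelium. Before that, each donor's cells had received a lentivirus carrying a doxycycline-inducible gene for either EGFP, a fluorescent protein used as the control, or DN-GRHL2, a dominant negative form of GRHL2. GRHL2 is a grainyhead transcription factor that maintains junction and barrier genes of epithelia. Doxycycline was given from day 7 to day 14 at the interface, and RNA collected after these 7 days was measured on 6 oligonucleotide arrays, 3 per construct. Each donor contributed 1 EGFP and 1 DN-GRHL2 array, so the comparison was made within 3 donor pairs. The 6 arrays had medians of 6.72 to 6.79 on the log2 scale. Their number limits the precision of every value given here.

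The first question was how the grainyhead genes themselves differed between the constructs. GRHL2 signal stood at 11.46 ± 0.10 (SD, n = 3) on the log2 scale with EGFP and at 9.59 ± 0.53 (SD, n = 3) with DN-GRHL2. The difference was -1.87 ± 0.22 (SE) on the log2 scale, 3.65-fold lower, and was negative in all 3 pairs at -2.00, -2.30 and -1.31. GRHL1, a paralog that acts on many of the same epithelial genes, differed by -1.13 ± 0.12 (SE), and GRHL3, the paralog best known from the epidermal barrier, by 1.59 ± 0.21 (SE). Both also kept 1 sign in all 3 pairs. A second, dimmer GRHL1 probe set differed by -0.97 ± 0.31 (SE), with -0.18, -1.71 and -1.01 in the pairs. Its adjusted p was 0.355 by limma over all probe sets. By limma over all genes the adjusted p was 0.0861 for GRHL2, 0.0817 for GRHL1 and 0.0965 for GRHL3, above the 0.05 threshold. When donor was fitted as a random effect in limma, with the same log2 differences, GRHL2 and GRHL3 passed it with adjusted p of 0.0266 and 0.0417, and GRHL1 did not, with 0.0518. GRHL2 had 1 probe set, and the sources used here do not say whether it lies within the sequence of the construct, so its value is the signal of that probe set and not a measure of the construct's expression.

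**Figure D1:**
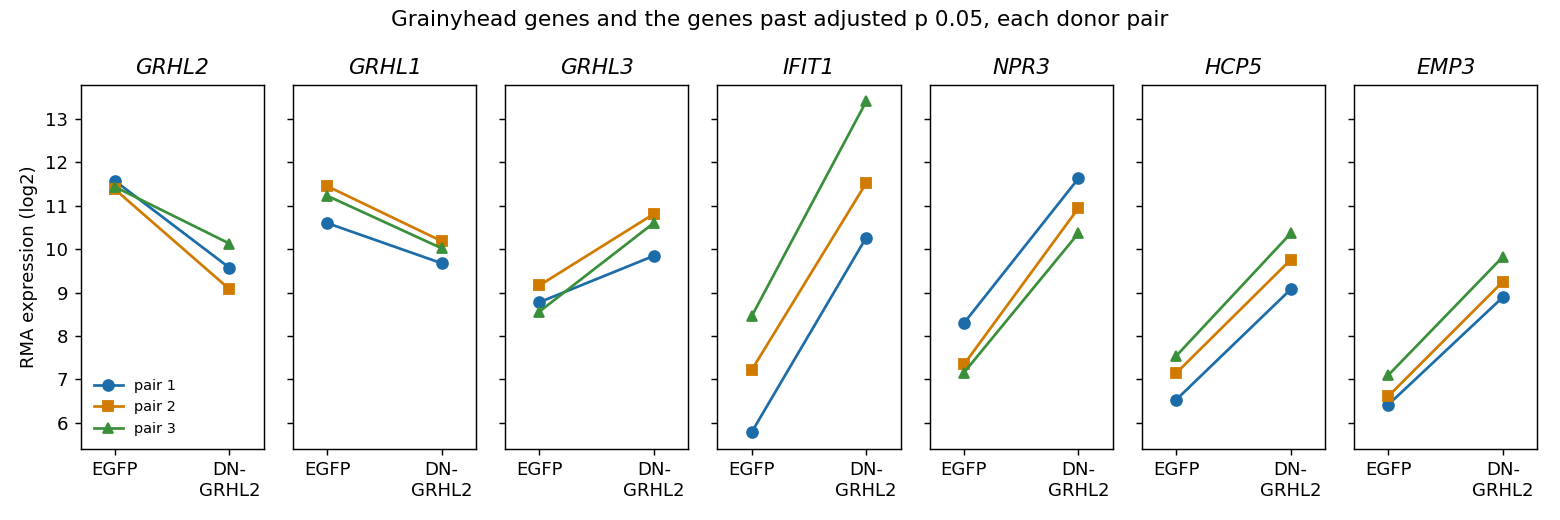
RMA expression (log2, vertical axis) of GRHL2, GRHL1, GRHL3 and the 4 genes past the threshold, with EGFP on the left and DN-GRHL2 on the right of each panel. Each line joins the 2 arrays of 1 donor pair. GRHL2 and GRHL1 lie lower with DN-GRHL2 in every pair, and the other 5 genes higher in every pair.

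Over all 13818 genes tested, 4 rose with DN-GRHL2 and 0 fell. IFIT1, an interferon-induced protein that binds viral RNA, rose by 4.58 ± 0.16 (SE) on the log2 scale, or 23.9-fold, with 4.48, 4.31 and 4.95 in the 3 pairs. NPR3, the clearance receptor for natriuretic peptides, rose 10.4-fold, by 3.38 ± 0.12 (SE) on the log2 scale. HCP5, a transcript from the region of the class I histocompatibility genes, rose 6.32-fold, by 2.66 ± 0.11 (SE), and EMP3, a membrane glycoprotein, rose 6.12-fold, by 2.61 ± 0.11 (SE). Each of the 4 had an adjusted p of 0.0282 by limma with donor as a block and was higher in 3 of 3 pairs. At an unadjusted p under 0.05 limma gave 1285 genes higher and 821 lower, against 690.9 in all by chance. Without pairs 1, 2 and 3 it gave 1609, 897 and 624 genes higher and 1098, 566 and 505 lower. Leaving out any donor left 0 genes past the threshold, in fits with 1 residual degree of freedom. At an adjusted p under 0.10 these fits gave 524 without pair 1, 0 without pair 2 and 0 without pair 3. With donor as a random effect 97 genes rose and 94 fell, the same 4 among them, and with no block 10 rose and 9 fell, none of the 4 among them.

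At an adjusted p under 0.10 by limma, 123 genes were higher, the 4 above among them, and 97 were lower, all with 1 sign in the 3 pairs. The differences of those that missed the 0.05 threshold are given here as values. Those with the lowest values were PROM1 at -2.54 ± 0.36 (SE) and PROM2 at -2.37 ± 0.27 (SE), which encode prominins, glycoproteins of membrane protrusions. RAB25 stood at -1.96 ± 0.28 (SE) and RAP1A, a small GTPase of cell adhesion, at -2.01 ± 0.19 (SE). The RAP1A probe set stood at 14.56 with EGFP, near the highest value on any array, 14.92. Whether it also sees other genes was not checked, so its value is uncertain. TMEM256 differed by -2.06, TMEM40 by -1.95, RHNO1 by -1.89, SLC44A2 by -1.71 and SPRR1A, a precursor of the cornified envelope, by -1.68. The 10 lower genes with the smallest p were TMEM40, WDR5B, RAB27B, ANKRD36B, LXN, CRABP2, TMEM256, RHNO1, STRADA and TMPRSS11E. In that set, the secretory GTPase RAB27B differed by -1.45, the retinoic acid carrier CRABP2 by -1.39, the carboxypeptidase inhibitor LXN by -1.54 and the serine protease TMPRSS11E by -1.53. WDR5B stood at -1.59, ANKRD36B at -1.50 and STRADA at -1.19. Among the higher genes, C11orf96 stood at 3.54, PPP2R2C, a regulatory subunit of a protein phosphatase, at 3.09, TNNT1, a troponin of slow skeletal muscle, at 3.05, FIBIN at 2.90 and the adhesion molecule CLMP at 2.89. PPP2R2C and TNNT1 had means of 6.34 and 5.73 with EGFP, and WDR5B and TMPRSS11E of 6.40 and 6.18 with DN-GRHL2, under the 6.56 below which genes were left out as dim. Such differences are lower bounds as far as that signal is background, which was not measured. With donor as a random effect PROM1, RAB25, SPRR1A, WDR5B, RAB27B, ANKRD36B, LXN and CLMP missed the 0.05 threshold, with adjusted p of 0.0518 to 0.199, and the other genes named in this group passed it.

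Genes of the interferon response moved together. Of the 26 members tested, 26 had a positive difference and 25 were higher in every pair, and the list median was 2.06 on the log2 scale. Over all genes 1 member, IFIT1, rose, and adjusted over the list alone 24 rose, 0 fell and 2 did not pass. RSAD2, an antiviral enzyme, rose by 3.91 ± 0.68 (SE) on the log2 scale, IFI6 by 3.68 ± 0.27 (SE), IFI44L by 3.58 ± 0.53 (SE) and the mitochondrial nucleotide kinase CMPK2 by 2.84 ± 0.34 (SE), each adjusted over the list alone. The mean of RSAD2 with EGFP, 6.10, also lay under 6.56. The 24 members became 25, 22 and 23 without pairs 1, 2 and 3, 23 with donor as a random effect and 15 with no block. The list shift differed in size between pairs, with medians of 1.03, 1.60 and 3.57. Limma's camera gave an adjusted p of 6.29e-17 with its preset correlation and an adjusted p of 0.749 with an estimated correlation, a test with 2 residual degrees of freedom here and for every list. Markers of leukocytes, which also express such genes, had a median of -0.04 over the 6 members tested (camera adjusted p = 0.970). One of them, CD14, a receptor for bacterial lipopolysaccharide that epithelia also make, rose by 2.72 ± 0.29 (SE), adjusted over the list alone.

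**Figure D2:**
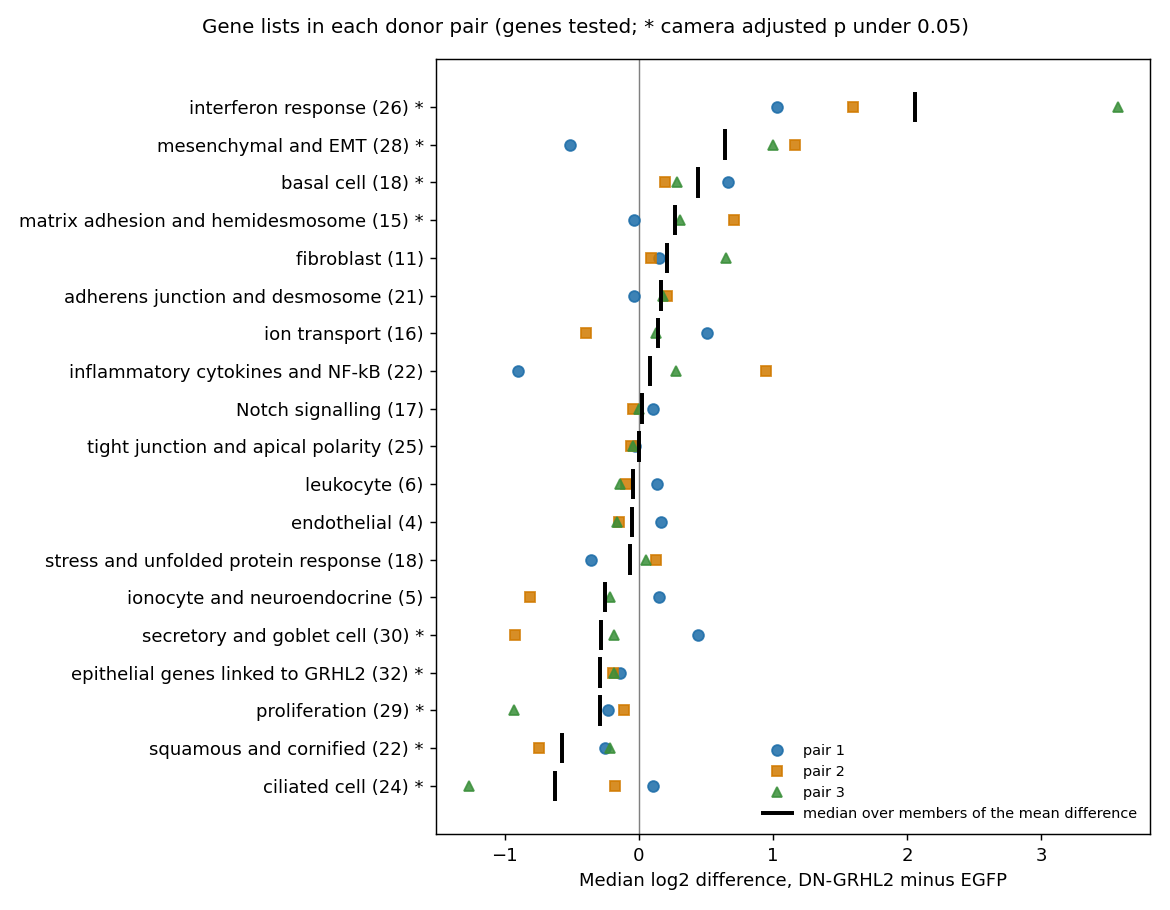
Median log2 difference, DN-GRHL2 minus EGFP (horizontal axis), over the tested members of each of the 19 gene lists (vertical axis). Symbols are the medians of the 3 donor pairs, black bars the medians over members of the mean difference, and a star marks a camera adjusted p under 0.05 with the preset correlation. The interferon list lies to the right in all pairs, and the mesenchymal list lies to the left in pair 1 at -0.51 and to the right in pairs 2 and 3.

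The epithelial genes linked to GRHL2 were a list of genes known to depend on it or to act with it. Of 32 tested, 0 passed over all genes, and adjusted over the list alone 9 fell, 1 rose and 22 did not pass. The small GTPase RAB25, which recycles membrane to the cell surface, fell by 1.96 on the log2 scale, the epidermal differentiation factor ZNF750 fell by 1.57 ± 0.17 (SE) and GRHL1 fell by 1.13, and GRHL3 was the member that rose. OVOL1 and OVOL2, repressors of mesenchymal genes, fell by 0.93 and fell by 0.91, and the protease PRSS8 fell by 0.56, adjusted over the list alone. The 9 that fell became 5, 5 and 3 without pairs 1, 2 and 3, 10 with donor as a random effect and 8 with no block. The list median was -0.29 with an adjusted p of 0.00317 by camera, and an adjusted p of 0.749 with an estimated correlation. EHF, an epithelial transcription factor and the brightest member, differed by -0.22 ± 0.11 (SE), and DSP by 0.32 ± 0.14 (SE), neither past the threshold.

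Tight junction and apical polarity genes showed no common shift, with a median of -2.0e-04 over 25 members and a camera adjusted p of 0.344. One member passed when adjusted over the list alone, CGN, a cytoplasmic plaque protein of tight junctions, which fell by 0.73 ± 0.11 (SE) on the log2 scale. With pair 1 left out 3 members rose and 3 fell, and 0 passed without pair 2, without pair 3, with donor as a random effect or with no block. The claudins CLDN7 and CLDN1 differed by 0.27 ± 0.13 (SE) and -0.17 ± 0.26 (SE). Among 21 genes of adherens junctions and desmosomes, adjusted over the list alone, 2 rose and 2 fell and 17 did not pass. NECTIN4, an adhesion molecule of adherens junctions, fell by 1.12 ± 0.11 (SE) and the envelope protein EVPL fell by 0.84 ± 0.10 (SE), while the desmosomal genes DSG3 and PKP1 rose by 1.30 ± 0.27 (SE) and 0.74 ± 0.15 (SE). With donor as a random effect or no block 0 rose and 2 fell, with pair 1 left out 3 rose and 2 fell, with pair 2 left out 0 rose and 1 fell, and with pair 3 left out 0 passed. The median of this list was 0.17 (camera adjusted p = 0.400), and its brightest genes, PERP and DSP, differed by 0.17 ± 0.12 (SE) and 0.32 ± 0.14 (SE).

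Mesenchymal genes and genes of epithelial-mesenchymal transition had a median of 0.64 on the log2 scale over 28 members. Adjusted over the list alone 6 rose and 0 fell, and over all genes 0 passed. ZEB1, a repressor of epithelial genes, rose by 1.76 ± 0.29 (SE), the collagen cross-linking enzyme LOX by 1.44 ± 0.23 (SE), the integrin ITGA5 by 1.20 ± 0.18 (SE) and the receptor kinase AXL by 1.18 ± 0.13 (SE), and TGFB1 and NNMT rose by 0.85 and 1.12. The mean of ZEB1 with EGFP, 6.15, lay under 6.56. With pair 1 left out 18 members rose and 1 fell, with pair 2 left out 5 rose and 1 fell, and with pair 3 left out 2 rose, while 1 rose with donor as a random effect and 0 with no block. The bright members TGFBI and FN1 differed by 1.31 ± 0.33 (SE) and 0.99 ± 0.61 (SE) without passing. The pairs were unlike each other, with list medians of -0.51, 1.16 and 1.00, and on the EGFP array of pair 1 the list's median level was 11.85, against 9.32 and 8.59 on the other EGFP arrays. Among the 11 fibroblast markers tested the median was 0.21 (camera adjusted p = 0.172), with 8 positive and 3 negative. Adjusted over the list alone COL6A1 rose by 1.60 ± 0.27 (SE), while COL1A1 differed by 0.65 ± 0.74 (SE) and FBLN1 by 0.21 ± 0.21 (SE). DCN and COL1A2 differed by 2.60 and 2.06 without passing. Of these markers 4, 3 and 0 rose without pairs 1, 2 and 3, and 0 with no block. For the mesenchymal list camera gave an adjusted p of 0.0159, and an adjusted p of 0.749 with an estimated correlation. The call was also lost without pair 2 (0.318), without pair 3 (0.141), with no replicate block (0.104) and with the mean of each gene's probe sets (0.0529).

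**Figure D3:**
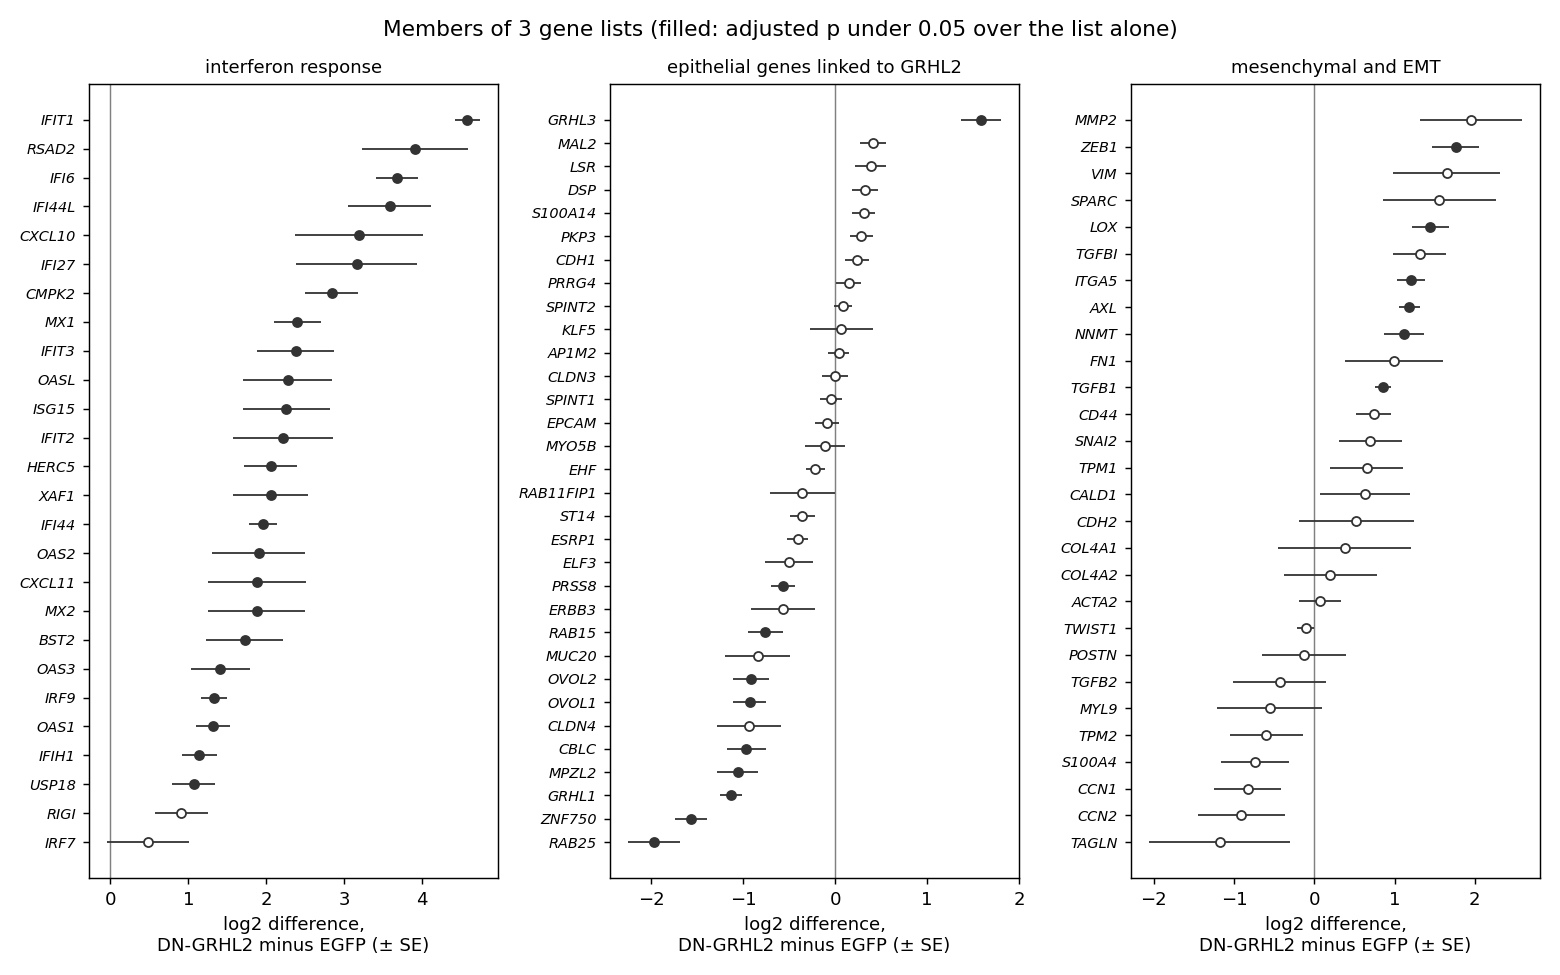
Log2 difference, DN-GRHL2 minus EGFP, with its SE (horizontal axis) for each tested member (vertical axis) of the interferon, GRHL2-linked and mesenchymal lists. Filled points have an adjusted p under 0.05 over the list alone, which holds for 24, 10 and 6 members, and open points do not.

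Genes of matrix adhesion and hemidesmosomes, by which basal cells hold to the basement membrane, had a median of 0.27 over 15 members. The pair medians were -0.03, 0.71 and 0.31. The laminin-binding integrin chains ITGA6 and ITGA3 rose by 1.30 ± 0.19 (SE) and 1.00 ± 0.12 (SE), adjusted over the list alone, and 13 members did not pass. With pair 1 left out 6 rose and 1 fell, and 0 passed without pair 2 and 1 without pair 3. ITGB1 and LAMB3 differed by 0.27 and 0.44. The camera adjusted p was 0.0125, the adjusted p was 0.749 with an estimated correlation, and it was 0.271 without pair 2. Basal cell markers had a median of 0.44 over 18 members, of which 4 rose and 1 fell when adjusted over the list alone. PDPN, a mucin-like membrane protein, rose by 1.86 ± 0.44 (SE), the growth factor receptor EGFR by 0.88 ± 0.12 (SE) and KRT14 by 0.67 ± 0.11 (SE), while KRT5, the other main basal keratin, fell by 0.87 ± 0.16 (SE). With donor as a random effect or no block 1 rose and 0 fell, and without pairs 1, 2 and 3 there were 5, 3 and 2 that rose and 2, 1 and 0 that fell. AQP3 and S100A2 differed by 0.45 ± 0.45 (SE) and -0.16 ± 0.10 (SE). The camera adjusted p of 0.0103 became 0.104 without pair 1 and 0.0654 with no replicate block, and the adjusted p was 0.749 with an estimated correlation.

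Ciliated cell genes had a median of -0.62 over 24 members, 22 of them negative, with 0 past the threshold over all genes or adjusted over the list alone. The bright members CCNO, a regulator of centriole amplification, and SPAG16, a protein of the ciliary axoneme, differed by -1.45 ± 0.39 (SE) and -0.15 ± 0.14 (SE). The shift lay mainly in pair 3, with pair medians of 0.10, -0.18 and -1.27. The EGFP array of pair 3 had the highest ciliated median of the 6 arrays, at 8.87. The EGFP arrays of pairs 1 and 2 stood at 6.68 and 7.12, so these pairs had little ciliated signal to lose. Camera gave an adjusted p of 5.48e-04, which became 0.150 without pair 3, and the adjusted p was 0.749 with an estimated correlation. Proliferation genes had a median of -0.29 over 29 members, 28 of them negative and 16 lower in every pair, and again 0 passed alone. Their shift too was largest in pair 3, with pair medians of -0.23, -0.11 and -0.93. The EGFP array of pair 3 had the highest proliferation median of the 6 arrays, at 8.81. TOP2A, a topoisomerase of dividing cells, differed by -1.20 ± 0.32 (SE), PCNA by -0.22 ± 0.11 (SE) and MCM4 by -0.19 ± 0.11 (SE); TOP2A was chosen after its values were seen. The camera adjusted p was 5.61e-07, and the adjusted p was 0.749 with an estimated correlation.

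Secretory and goblet cell genes had a median of -0.28 over 30 members and pair medians of 0.44, -0.92 and -0.18. On the EGFP array of pair 1 the list's median level was 9.24, against 12.26 and 12.76 on the other EGFP arrays. The 1 member that passed when adjusted over the list alone, TFF1, a trefoil peptide of mucous cells, rose by 1.35 ± 0.13 (SE), against the direction of the list. With pair 1 left out 6 fell and 1 rose, with pair 2 left out 1 fell and 1 rose, and 0 passed without pair 3, with donor as a random effect or with no block. LCN2 and SLPI, the brightest members, differed by -0.10 ± 0.12 (SE) and -0.10 ± 0.21 (SE). The camera adjusted p of 0.0313 became 0.930, with the direction turned, without pair 2, and the call was lost with no replicate block at 0.181, with no filter at 0.0954 and with mean probe sets at 0.0529. The adjusted p was 0.749 with an estimated correlation. Squamous and cornified genes had a median of -0.57 over 22 members, of which 2 fell and 1 rose when adjusted over the list alone. The pair medians were -0.25, -0.75 and -0.21. The EGFP array of pair 1 had a median level of 9.53 for this list, against 11.77 and 11.28 on the other EGFP arrays. The cornified envelope precursors SPRR1A and SPRR1B fell by 1.68 ± 0.22 (SE) and fell by 1.59 ± 0.32 (SE), and the kallikrein protease KLK10 rose by 0.96 ± 0.12 (SE). With pair 1 left out 7 fell and 2 rose, with pair 2 left out 3 fell and 1 rose and with pair 3 left out 1 fell, while 0 passed with donor as a random effect or with no block. SERPINB3 and S100A9 differed by 1.06 ± 0.87 (SE) and -0.83 ± 0.23 (SE). The camera adjusted p was 0.0313, and it was 0.203 without pair 2, 0.0981 with no replicate block and 0.0599 with no filter. The adjusted p was 0.749 with an estimated correlation.

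Ion transport genes were not called as a list, with a median of 0.14 over 16 members and a camera adjusted p of 0.400, yet 4 rose and 1 fell when adjusted over the list alone. CA2, a carbonic anhydrase, rose 10.8-fold, by 3.43 ± 0.33 (SE) on the log2 scale. The calcium-activated potassium channel KCNN4 rose by 2.10 ± 0.28 (SE), the calcium-activated chloride channel ANO1 by 1.97 ± 0.38 (SE) and the sodium channel subunit SCNN1G by 1.74 ± 0.41 (SE), while the sodium-potassium-chloride cotransporter SLC12A2 fell by 0.47 ± 0.10 (SE). The mean of SCNN1G with EGFP, 6.26, lay under 6.56. The 4 that rose became 3, 6 and 3 without pairs 1, 2 and 3, 4 with donor as a random effect and 3 with no block, and without pairs 2 or 3 none fell. ATP1B1 and SCNN1A differed by -0.07 ± 0.14 (SE) and 0.18 ± 0.17 (SE). Of 22 inflammatory cytokine and NF-kB genes, the chemokine CXCL6 fell by 1.53 ± 0.23 (SE), adjusted over the list alone, and 21 did not pass. With pair 1 left out 3 rose and 1 fell, with pair 2 left out 4 rose and 3 fell, and 0 passed without pair 3, with donor as a random effect or with no block. C3 differed by 0.53 and CXCL8 by -0.18, and the list median was 0.08 (camera adjusted p = 0.344).

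In 4 lists no member passed and the list was not called, though in 3 of them up to 3 members passed, adjusted over the list alone, with donor as a random effect, with no block or with a pair left out. These were Notch signalling, with a median of 0.02 and a camera adjusted p of 0.741, stress and unfolded protein response, at -0.07 and 0.303, endothelial markers, at -0.05 and 0.400, and ionocyte and neuroendocrine markers, at -0.25 and 0.246. Their brightest genes were JAG1 at 0.02 and NOTCH2 at 0.17, HSPA5 at 0.25 and GADD45A at 0.34, ESAM at -0.04 and PECAM1 at -0.02, and UCHL1 at 1.57 ± 0.59 (SE) and ASCL3 at -0.62 ± 0.49 (SE). In the leukocyte list the other bright member, CD79A, differed by -0.01.

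Over the whole array, 27.5% of the sum of squares of the tested genes followed the construct, 51.4% the donor and 21.1% neither. The first principal component held 52.7% of the variance and the second 26.2%. DN-GRHL2 arrays were more alike than EGFP arrays, with Pearson correlations across genes of 0.958 to 0.984 against 0.880 to 0.964, genes not being independent replicates. Correlations within a donor pair were 0.948 to 0.955. Arrays with no effects would also give each term a share, larger for the donor, which takes more degrees of freedom than the construct. The shares are therefore not effect sizes, and no test was made of them.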

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

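The tests of the 3 patterns in this part were chosen after the results were seen, except the count of other splits. One measurement outside the report stood out: of 13522 probe sets with no gene or several genes in the annotation, 1 was higher with DN-GRHL2 by limma over all probe sets, by 2.26 ± 0.09 (SE) on the log2 scale (adjusted p = 0.0357, n = 3 pairs), and 0 were lower. At an adjusted p under 0.10 there were 4, all higher. No explanation was tested for it.

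The number of arrays limits what other splits can show. The 6 arrays can be split into groups of 3 in 10 ways, so no share under 0.05 can be reached. The real split gave 4 genes past the threshold and was the only 1 of the 10 to reach that number, the highest other count being 0. Among the 4 splits that part all donor pairs, the real split called 9 gene lists against at most 8, and gave 2106 genes at an unadjusted p under 0.05 against at most 856. Each of the others among these 4 exchanges the constructs of 1 pair and so still holds the real difference. The interferon list median was -0.10, 0.88 and -1.30 in them. The -1.30 belongs to the split that exchanges pair 1, with its groups labelled the other way round. Its minus sign comes from this labelling alone: labelled as the others, its median is positive and of the same size. The exchange also adds to the spread within the fit, which lowers their gene counts. The remaining 6 splits part 1 pair each, and with the donor block each of them estimates the construct difference of that pair alone. These 6 carry the real difference too, so none of the other splits is a comparison without an effect. With the 6 included, 3 of the 10 splits, the real one among them, called as many lists or more, the highest other count being 10. The others at 10 lists are the same fit of pair 2 with the sign turned, so they are not separate results.

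The interferon list was higher with DN-GRHL2 in all 3 pairs, by a median of 2.06 on the log2 scale. RNA from leukocytes stays open: the 6 of their 14 markers tested had a median of -0.0418 (SD 1.14), but only 1 of them, CD14, lay above the median level of all genes, and it was higher by 2.72. The lowest list median under 3 other scalings between arrays was 2.03. As the array medians were 6.72 to 6.79 beforehand, these scalings could hardly have moved a shift of this size, so they decide little. The median difference over all tested genes was 0.02, so an offset shared by all genes would be small beside the list's shift. A biological response to the DN-GRHL2 protein stays open as a hypothesis, as does a difference in virus dose between the constructs, which no value here tests; both groups had received a lentivirus. With an estimated correlation between members, 0.897, the list is not called (adjusted p = 0.749 on 2 residual degrees of freedom, and 0.209 on those of the preset test), so the 26 genes count as few independent measurements.

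The ciliated and proliferation lists were lower with DN-GRHL2. The ciliated shift lay mainly in pair 3. Over pairs 1 and 2 the median was -0.0366 (camera adjusted p = 0.150), with pair medians of 0.10 and -0.18. In every pair 6 of 24 members were lower, against 5.75 expected if only pair 3 differed. The ciliated median level was 6.68 and 7.12 on the EGFP arrays of pairs 1 and 2, against 8.87 in pair 3. Pairs 1 and 2 thus had little ciliated signal to lose. They cannot tell a difference in pair 3 alone from an effect in all donors, so both stay open. For proliferation genes 16 of 29 members were lower in every pair, against 7.25 expected, and 22 were lower over pairs 1 and 2. Over these pairs camera gave an adjusted p of 0.00325 with its preset correlation and of 0.790 with an estimated correlation. The counts go against a difference in pair 3 alone. It is not excluded, as the median over pairs 1 and 2, -0.20, lay within the spread of the members (SD 0.34), which are not independent. Degraded RNA on the DN-GRHL2 array of pair 3 is argued against by the control probe sets, where the 3' to 5' gap of GAPDH and ACTB was wider than on its EGFP partner by at most 0.0742 on the log2 scale. Whether the construct acts on ciliated cells, or the EGFP culture of that pair held more of them, stays open.

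The mesenchymal list was higher in pairs 2 and 3, by a median of 1.12 over both, and not in pair 1. RNA from fibroblasts stays open: the 14 fibroblast markers had a median of 0.0417 (SD 1.11) in these pairs, but 5 were higher by at least 1, COL1A2 among them at 3.33, and 9 lay within 0.25 of 0. Most of these 9 were dim with EGFP and with DN-GRHL2, such as COL3A1 at 6.30 and 6.36 and LUM at 6.80 and 6.82. FBLN1, at 9.91 and 10.09, was not. Whether the dim probe sets would see fibroblast RNA is not known, so the median decides little. The control array of pair 1 stood apart: its list median was 2.53 above the higher of the other EGFP arrays, while the DN-GRHL2 array of that pair lay 0.68 above the others. Fibroblast collagens stood high on the same control array, COL1A1 at 12.33 against 9.42 and 8.12 and COL1A2 at 10.91 against 7.05 and 5.22. DCN at 6.39 did not, against 6.43 and 6.87. On the DN-GRHL2 arrays of pairs 1, 2 and 3 DCN stood at 10.70, 8.44 and 8.35, higher than its control in every pair, pair 1 included. The missing rise of the list goes with a high control level in pair 1 and not with a low DN-GRHL2 level. A pair's difference is its DN-GRHL2 level minus its control level, so these values restate the pattern and cannot show its reason. Whether the control level comes from the donor, the culture or fibroblasts in it was not tested.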

How the results depend on the processing

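The same 4 genes passed with a variance trend, a robust prior, other filters, other probe set rules, 3 other scalings and a 1.5-fold minimum. The count was 191 with donor as a random effect, 19 with no replicate block (all 4 lost), 220 at an adjusted p under 0.10, 0 under 0.01, and 0 to 0 without each replicate, where 1 residual degree of freedom per gene is left. Added after the data were seen, an unadjusted p under 0.05 gave 2106, and no replicate block without EGFP replicate 1 gave 51 (29 higher, 22 lower). Higher genes made up 100% of the calls in the report, 52.6% with no replicate block and 50.8% with the random effect. The first component's share was 42.0% with genes scaled to unit variance. GRHL1, GRHL2 and GRHL3 kept their sign in every alternative. GRHL2 and GRHL3 passed with donor as a random effect, and all 3 had an adjusted p under 0.10 in the main fit.

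Of the 9 lists called, 0 were called with an estimated correlation (adjusted p = 0.749 for each), a test that also drops to 2 residual degrees of freedom, 0 by directional fry and 5 with no replicate block. Mixed fry, which tests for change in either direction, called 11 lists, 5 of the 9 among them. With the estimated correlation and the degrees of freedom of the preset test, added after the data were seen, 1 list was called, GRHL2-linked (0.00188). The estimated correlation of this list was -0.0025, below the preset one, so for it this test was the easier of them. Its unadjusted camera p was 9.89e-05, against 6.67e-04 with the preset correlation. Directional fry gave 0.232 for GRHL2-linked, 0.283 for interferon, 0.600 for mesenchymal and ciliated, 0.791 for secretory and 0.524 for matrix adhesion, basal, squamous and proliferation genes. With no replicate block the adjusted p was 0.104 for mesenchymal, 0.0654 for basal, 0.181 for secretory and 0.0981 for squamous genes. With mean probe sets it was 0.0529 for mesenchymal and secretory genes, and with no filter 0.0954 for secretory and 0.0599 for squamous genes. Without each replicate in turn it ranged from 1.77e-08 to 0.318 for mesenchymal, 1.02e-04 to 0.271 for matrix adhesion, 0.00253 to 0.104 for basal, 7.42e-06 to 0.930 for secretory (turned without replicate 2), 2.93e-06 to 0.150 for ciliated and 0.00287 to 0.203 for squamous genes. The interferon, GRHL2-linked and proliferation lists were called with any 1 replicate left out.

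Lists that were not called turned direction without 1 replicate, with adjusted p of 0.00579 to 0.973 for ion transport, 4.77e-04 to 0.393 for inflammatory, 0.0124 to 0.873 for stress and 0.511 to 0.873 for leukocyte genes. Leukocyte genes also turned with no filter (0.349) and mean probe sets (0.796), and ionocyte genes with mean probe sets (0.987). Of 614 settings of single genes 575 had the direction and the side of the threshold given in the report, and 16 turned sign, all in genes that did not pass. Without each replicate their log2 differences ranged from -0.47 to 0.14 for CLDN1, -0.19 to 0.87 for AQP3, -0.37 to 0.0660 for SLPI, -0.23 to 1.77 for SERPINB3, -0.18 to 0.0754 for ATP1B1, -0.0023 to 0.36 for SCNN1A, -0.16 to 0.16 for JAG1, -0.75 to 0.32 for CXCL8, -0.0185 to 0.47 for FBLN1, -0.12 to 0.17 for CD79A, -0.20 to 0.0400 for ESAM and -0.15 to 0.11 for PECAM1. JAG1 stood at -0.00958 with mean probe sets and CD79A at 0.00087 with median centring. The cause was not tested for any of these.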

Other observations

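A set of 5 gene groups outside the fixed lists was examined after the data were seen. Genes of class I antigen presentation, which interferons induce, had a median of 0.82 on the log2 scale over 14 members, 13 of them positive and 12 higher in every pair. Adjusted over the list alone 8 rose, among them NLRC5, the transactivator of these genes, by 1.22 ± 0.20 (SE) from a mean under the level of the filter, and the immunoproteasome subunit PSMB9 by 1.09 ± 0.31 (SE). Class I genes share probes, so their separate values are uncertain and only the group is given. Limma's camera over 24 lists gave an adjusted p of 1.56e-07 and an adjusted p of 0.727 with an estimated correlation. Of 7 class II genes 1 passed when adjusted over the list alone, and the list was not called (median 0.43, adjusted p = 0.431).

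Histone genes, grouped as replication-dependent, had a median of 0.12 over 23 members, although H1-10 among them is not replication-dependent. When adjusted over the list alone 16 did not pass and 7 rose, H4C8 by 2.19 ± 0.35 (SE), H2BC21 by 1.60 ± 0.24 (SE) and H1-2 by 1.27 ± 0.11 (SE). The adjusted p of this group by camera was 9.28e-04, and it was 0.727 with an estimated correlation. Near-identical histone genes can share probes. Cholesterol synthesis genes had a median of -0.45 over 12 members, 11 of them negative and 7 lower in every pair, with 0 past the threshold when adjusted over the list alone. The pair medians were -0.71, -0.06 and -0.61. INSIG1, a sterol sensor partner, differed by -0.68 ± 0.14 (SE), and camera gave an adjusted p of 3.26e-04 for the list and an adjusted p of 0.735 with an estimated correlation. Of 10 glucocorticoid-responsive genes, FKBP5 rose by 1.98 ± 0.19 (SE) and SGK1 fell by 1.29 ± 0.18 (SE), adjusted over the list alone, and the list was not called (median 0.21, adjusted p = 0.308).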
